A study of Caenorhabditis elegans with 4 samples.

How the data were processed

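Total RNA of C. elegans grown at 20 degrees was gel-selected for small RNAs, treated with tobacco acid pyrophosphatase, which opens triphosphorylated 5′ ends for ligation, ligated to a 3′ linker and to a 5′ adapter carrying a barcode, amplified and sequenced on a Genome Analyzer IIx, per the labels' protocols. Each library had its own barcode, so barcode and library cannot be told apart. Per the file headers, each deposited table lists a distinct sequence and its number of reads, so the unit is counts of reads per sequence, not normalized by the authors. The aligner, genome build and filters are not given in the sources used here. The 4 tables held 4327777 distinct sequences, of which 88924 occurred in every library, and between 63.3% and 78.6% of a library's distinct sequences had 1 read. For the 20 most abundant miRNAs, 9.00% to 11.2% of full-length reads carried 1 substitution, so the tables are not limited to error-free copies of known sequences.

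The planned analysis placed reads on genes. The reference held an annotation (WBcel235, Ensembl) and a table of gene names, and no genome sequence was used here, so reads could not be mapped, and the unit of analysis was changed after the files were seen. The per-gene lists other than miRNAs, multiply mapped reads, rRNA and tRNA removal and the rde-12 locus were not analysed. Scaling was therefore to reads per 1000000 of all reads in the file (RPM), in place of mapped reads without rRNA and tRNA.

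The cpsf-2 contig was assembled with a greedy extension of words of 15 nt. The seed was the most abundant sequence with 0 reads on L4440 food and at least 5 reads in each cpsf-2 RNAi library. A word's score was its reads on cpsf-2 RNAi food less 3 times its reads on L4440 food, on both strands, the choice between the 2 best continuations was made by looking 8 nt ahead, and extension stopped under a score of 3. Of the 414 sequences that met the seed rule, 66 lie on the contig. Reads were assigned to the contig by exact match. Its identity rests on the food's label and on the alignment to human CPSF2 (BLOSUM62). That protein, the other proteins named in the closing part, the 5S rRNA and the mature miRNA sequences were written from general knowledge and not taken from a reference file. Reads of 20 nt or more were matched to proteins by translating both strands in all frames, and the reversed proteins gave the background.

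A miRNA was used when its sequence was the most abundant read with its first 20 nt, had at least 40 reads in that sum, and had a length the annotation gives for a mature product of that gene. Of 97 sequences written, 81 were used. For let-7 no mature transcript under that name was found, so its length was not compared. A few 3′ ends were set knowing the common read. Counts are of reads starting with the first 20 nt, and copies with the same mature sequence are not told apart. mir-84, mir-34, mir-244, mir-246, mir-1834 and mir-2209 of the fixed lists were not measured. Coordinates are those of WBcel235.

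Reads of 21 to 23 nt starting with G, with at least 2 reads in all and no miRNA match, were joined into clusters when they shared a word of 17 nt. The 514598 sequences, 83.5% of 22G reads, formed 262443 clusters. Word lengths from 15 to 18 nt were tried on the data before 17 was chosen. A cluster can hold part of a gene, and near-identical copies of a gene or repeat merge.

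Clusters and miRNAs were tested with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood F-test) in R 4.3.3 with food and genotype as additive terms over the 4 libraries. This leaves 1 residual degree of freedom, and the spread is the extent to which the genotype effect differs between foods. A p-value thus measures spread between these single libraries and not between cultures. DESeq2 1.42.0 was an alternative. Contrasts between single libraries have no test. Their intervals are exact Poisson, Clopper-Pearson or conditional binomial, and the ratios of ratios use a normal approximation on the log scale. Size-rule ratios used a pseudocount of 1 RPM. Other work used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, Biopython 1.88 and Matplotlib 3.10.9.

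The edgeR step was tested on simulated counts for the genotype comparison. With a low spread (dispersion 0.05) on 16337 clusters it called 80 of 100 clusters changed 4-fold and 100 of 100 changed 16-fold, with 9 unchanged clusters called. With the common dispersion of the real clusters (0.583) given to each of 15069 clusters it called 0 of 100 at 4-fold and 0 of 100 at 16-fold. For miRNAs at the low spread it called 6 of 6 at either size among 81, and at the common dispersion of the real miRNAs (0.626) it called 0 of 6 at either size among 80. In the real fit the spread differs between features, so these counts do not give its power. A count of 0 calls is thus no evidence that values did not differ.

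The rule for named features was fixed before the data were examined. It takes the largest fitted changes past an adjusted p of 0.05 with the same sign on both foods and at least 10 RPM in a library, cpsf-2 and rde-12 always, the 5 miRNAs per direction with the largest smaller within-food ratio among those with 100 RPM in a library, and up to 4 abundant members per list. Since clusters carry no names, 2 per direction are printed. miRNA lists, tests and most alternatives were also fixed then; the clusters, the contig, the protein matches and the alternatives named as such in the closing part were chosen after seeing the data.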

Results

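Small RNAs were sequenced from Caenorhabditis elegans in 4 groups that cross genotype with food. Wild-type worms and rde-12 mutants were each fed bacteria carrying the empty feeding vector L4440 or bacteria making double-stranded RNA against cpsf-2. The series title names RDE-12 as a homolog of Vasa, a DEAD-box RNA helicase, in RNA interference. The gene cpsf-2 encodes a subunit of the cleavage and polyadenylation complex. Each group had 1 library, so no value has a replicate within its group, and intervals are 95% intervals that cover counting error only, since PCR copies of a molecule cannot be told from separate molecules. The libraries held 4365650 reads for wild type on L4440 food, 4074840 for wild type on cpsf-2 RNAi food, 3580620 for rde-12 on L4440 food and 4307834 for rde-12 on cpsf-2 RNAi food. Reads were 17 to 32 nt long, and 1 read stood for between 0.229 and 0.279 reads per 1000000 reads of its library (RPM).

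The first question was how small RNAs against the fed gene differ in rde-12 mutants. On cpsf-2 RNAi food, antisense small RNAs of cpsf-2 stood at 62416 RPM in wild type (interval 62174 to 62660) and at 755 RPM in rde-12 (interval 729 to 782), an 82.7-fold lower level in the mutant (79.8 to 85.6). Sense small RNAs of the same region were 589 RPM in wild type and 373 RPM in rde-12, a 1.58-fold lower level (1.48 to 1.68). There were therefore 106 antisense reads per sense read in wild type (102 to 110) and 2.03 in rde-12 (1.91 to 2.15). On L4440 food the antisense level was 14.7 RPM in wild type (11.3 to 18.7) and 299 RPM in rde-12 (281 to 318), and the sense level was 0.916 RPM and 4.75 RPM. The antisense level was thus 4258-fold higher on cpsf-2 RNAi food than on L4440 food in wild type (3334 to 5529) and 2.52-fold higher in rde-12 (2.36 to 2.71), the latter 1.64-fold (1.53 to 1.76) when scaled to miRNA reads. The rise in rde-12 came mostly from a short stretch of the region, given below. The ratio of the ratios by all reads was 1686 (1307 to 2175). This ratio and the rise in rde-12 take the 299 RPM of rde-12 on L4440 food as their baseline. Carry-over from the wild-type cpsf-2 RNAi sample into that library stays open (closing part), and the intervals do not cover it.

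These values come from a contig of 1264 nt that was assembled from the reads themselves, because no genome sequence was used here. The contig holds an open reading frame of 421 codons with 0 stop codons in frame, and its translation matched residues 154 to 540 of human CPSF2 at 185 of 433 aligned positions, an identity of 42.7%. The alignment score was 876, against at most 62 for 100 shuffled versions of the frame. The annotation places cpsf-2 (WBGene00017313, protein-coding, 9 exons) on chromosome V from 7179172 to 7182858 on the plus strand of WBcel235, and its coding sequence is 2529 nt long. The deposited sequences carry no coordinates, so contig positions are counted from 1 at the 5′ end of the mRNA strand, and which exons they fall in was not analysed here. The contig was built from reads that were more abundant on cpsf-2 RNAi food, so the food contrast is partly built into its choice. Most of these reads came from the wild-type library, so the genotype contrast on that food may be partly built in as well. A count that does not use the contig gave the same direction for antisense reads in 2 contrasts, that of the foods in wild type and that of the genotypes on cpsf-2 RNAi food. Reads whose antisense translation fell within human CPSF2 stood at 709 RPM in wild type and 16.02 RPM in rde-12 on cpsf-2 RNAi food, and at 20.6 RPM and 21.5 RPM on L4440 food. The reversed human protein, which serves as a background, gave 15.95 RPM and 12.5 RPM on cpsf-2 RNAi food and 21.8 RPM and 9.496 RPM on L4440 food. On L4440 food both genotypes had like levels (1.04-fold, 0.759 to 1.43) over backgrounds that differed between the libraries, so this count leaves the rde-12 excess of the contig on that food open. For the foods in rde-12 it gave 0.745-fold (0.530 to 1.04) on cpsf-2 RNAi food over L4440 food, a difference within counting error, and so does not carry the higher level seen on the contig. Nor does it bear on the sense level, since sense reads of human CPSF2 on cpsf-2 RNAi food were 18.4 RPM in wild type, not above the 21.4 RPM of the reversed protein, and 36.2 RPM in rde-12, against 17.9 RPM. The rde-12 gene itself (WBGene00010280, chromosome V from 13665389 to 13669292) and the genes next to cpsf-2 were not analysed here for the same lack of a genome sequence.

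That antisense reads of wild type on cpsf-2 RNAi food cover the contig is built into its assembly. Their length peaked at 22 nt, with 38.4% of antisense reads, and their most abundant sequence, GAAAATCCTGATTCCATATCCT at contig positions 537 to 558, reached 2515 RPM against 5.34 RPM in rde-12. Antisense reads of 21 to 23 nt starting with G, the form of secondary 22G-RNAs made by RNA-dependent RNA polymerase, stood at 28533 RPM in wild type and 204 RPM in rde-12. This was a 140-fold lower level in the mutant (131 to 150), and the mutant value was 1.34 times that of rde-12 on L4440 food (1.204 to 1.496). Scaled to miRNA reads the last ratio turned to 0.872 (0.783 to 0.973), so it has no firm direction. Antisense reads of 21 to 24 nt starting with another nucleotide differed by 50.7-fold (48.1 to 53.4). Sense reads peaked at 23 nt in both libraries, with 22.2% in wild type and 28.0% in rde-12. They were densest between contig positions 801 and 900, at 152.4 RPM in wild type and 127 RPM in rde-12. In rde-12 the remaining antisense reads gathered near the same stretch. Of 3253 antisense reads, 815 began at position 1008, where the wild-type profile scaled to the same total gives 20.7. This was also the top position of wild type on L4440 food, with 15 of 64 reads.

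**Figure D1:**
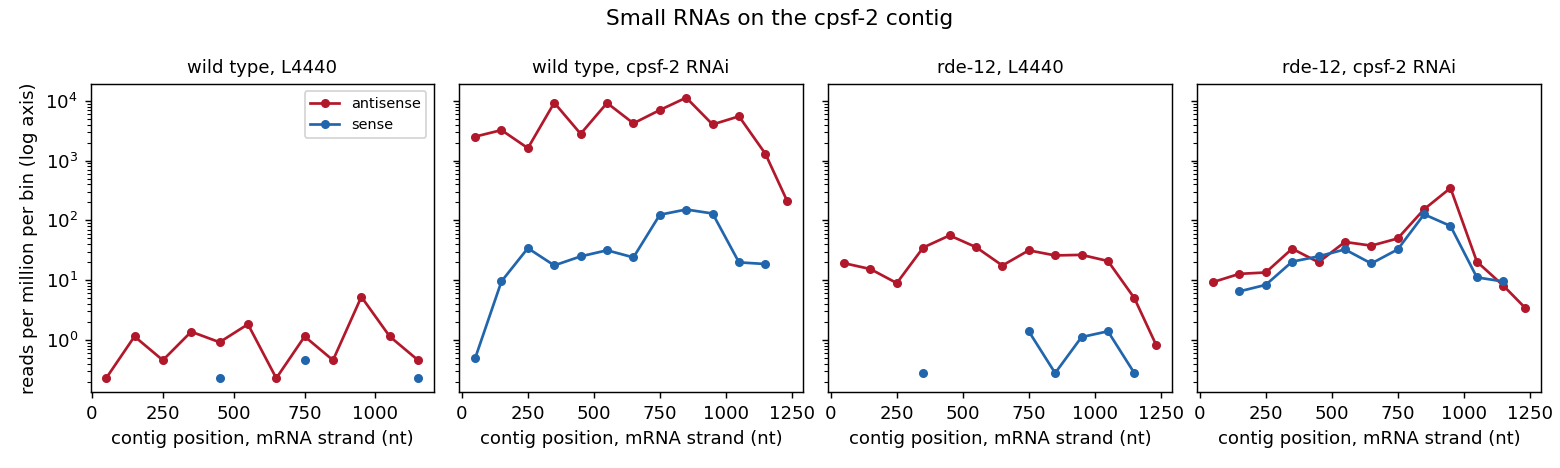
RPM (log axis) in bins of 100 nt along the cpsf-2 contig for the antisense (red) and sense (blue) strand, 1 panel per library; bins with 0 reads have no point. Between positions 801 and 900 the sense strand reached 152.4 RPM in wild type and 127 RPM in rde-12 on cpsf-2 RNAi food, while the antisense strand stood at 11334 RPM and 154 RPM.

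The composition of the small RNA population was compared next. The 21U class, reads of 21 nt starting with U that include the piRNAs of the germline, made up 3.73% of reads in wild type (3.71 to 3.75, exact Clopper-Pearson) and 8.37% in rde-12 (8.34 to 8.40) on L4440 food, and 3.74% (3.72 to 3.76) and 9.31% (9.29 to 9.34) on cpsf-2 RNAi food. The share was therefore 2.25-fold higher in rde-12 on L4440 food and 2.49-fold higher on cpsf-2 RNAi food. It differed little between foods within wild type, by 1.00-fold (0.996 to 1.01). Of 2886 single 21U sequences with at least 10 RPM in a library, 1741 were higher in rde-12 on both foods and 98 were lower on both. edgeR's quasi-likelihood test with TMM scaling called 0 of 4478 21U sequences, with 88 higher and 28 lower at an unadjusted p under 0.05, and no other tool was run. TMM takes a shift shared by the whole class as scaling, so the median log2 fold change was 0.15 under TMM, 1.68 scaled by library size (482 higher and 7 lower at an unadjusted p under 0.05) and 1.49 scaled to miRNA reads (391 and 10), with 0 called under each. As a share of distinct sequences in place of reads, the class was 1.27-fold higher in rde-12 on both foods.

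The 22G class, reads of 21 to 23 nt starting with G that were not matched to a miRNA, was 45.6% of reads in wild type and 32.2% in rde-12 on L4440 food, a ratio of 0.707 (0.705 to 0.708). On cpsf-2 RNAi food it was 34.8% in wild type and 37.1% in rde-12, a ratio of 1.07 that became 0.808 per miRNA read and 0.875 per read of 20 to 26 nt. The 26G class, 26-nt reads starting with G that include the primary siRNAs of endogenous pathways, was 0.477% in wild type and 1.31% in rde-12 on L4440 food, and 0.612% and 0.658% on cpsf-2 RNAi food. miRNA reads made up 13.3% in wild type and 13.2% in rde-12 on L4440 food, and 15.3% and 20.3% on cpsf-2 RNAi food. Reads of 17 to 19 nt differed widely between libraries and in opposite directions by genotype, at 7.96% in wild type and 23.8% in rde-12 on L4440 food and 19.5% and 2.80% on cpsf-2 RNAi food. miRNA reads that lacked their first nucleotides moved with them, as 7.26%, 15.8%, 13.6% and 0.803% of the sum of exact full-length and shortened reads in wild type on L4440 food, wild type on cpsf-2 RNAi food, rde-12 on L4440 food and rde-12 on cpsf-2 RNAi food.

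**Figure D2:**
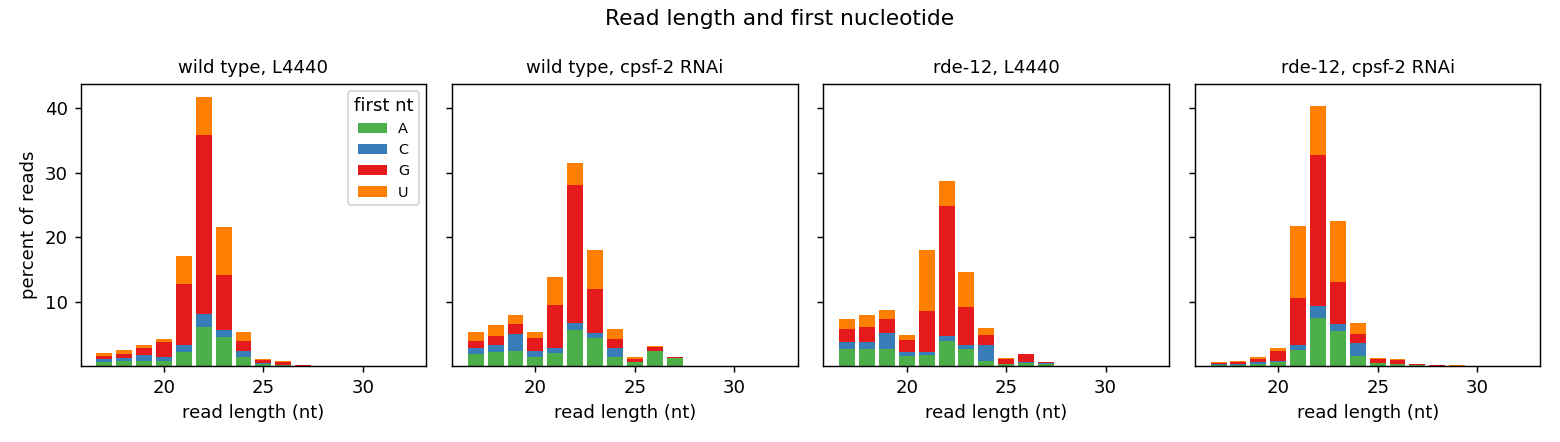
Percent of reads by length (nt) and first nucleotide (stacked colours), 1 panel per library. Reads of 17 to 19 nt range from 2.80% in rde-12 on cpsf-2 RNAi food to 23.8% in rde-12 on L4440 food.

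The 22G-RNAs as a whole were then compared between genotypes. Reads of this class that share 17 nt were joined into clusters, which stand in for genes because no read could be placed on the genome. Those against the fed gene were not left out. Of the 262443 clusters 15 lie on the cpsf-2 contig by most of their sequences. Clusters with fewer of their sequences on it were not counted, and clusters of cpsf-2 outside the contig could not be recognised. The 15 thus do not hold all 22G-RNAs of the contig. Its most abundant antisense sequence had 10247 reads in wild type on cpsf-2 RNAi food, while the 2 counted clusters that were tested had 337 and 3379. Of 10144 clusters with at least 10 RPM in a library, 1205 were lower by 2-fold or more in rde-12 on both foods and 1139 were higher by 2-fold or more on both. A further 467 were higher on L4440 food and lower on cpsf-2 RNAi food by this size, and 1296 were lower and then higher. The 467 include 2 of the clusters counted on the cpsf-2 contig, given below for food. Over all 10144 clusters the median log2 ratio was -0.61 on L4440 food and 0.50 on cpsf-2 RNAi food. The 1296 thus hold a shift shared by the whole set. Scaled to miRNA reads the 2 counts were 597 and 976. The lists parted at larger sizes. At 8-fold or more, 182 clusters were lower on both foods and 37 higher, while 13 and 6 moved in opposite directions. The 1205 lower clusters summed to 75189 RPM in wild type and 5716 RPM in rde-12 on L4440 food, and to 56630 RPM and 6000 RPM on cpsf-2 RNAi food. These sums follow from how the clusters were picked. Across clusters, which are not independent replicates, the genotype ratios of both foods had a Spearman correlation of 0.207.

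With the foods serving as the only repeats of the genotype contrast, edgeR's quasi-likelihood test called 82 clusters lower and 6 higher in rde-12 among 18327 tested (Benjamini-Hochberg adjusted p under 0.05), and 1150 and 652 at an unadjusted p under 0.05. Of the 82 lower clusters, 35 had 0 reads in both rde-12 libraries, and 5 of the 6 higher ones had 0 reads in both wild-type libraries. The cluster led by GTTACTAGTACGCTTTTATGCC had 18.6 RPM in wild type against 0 reads in rde-12 on L4440 food, at least 22.1-fold lower with 3 reads as the floor of each library. On cpsf-2 RNAi food it had 1444 RPM against 1 read (edgeR, adjusted p = 0.0107). The cluster led by GATCATTGTCTGGTTCTGGACT had 77.7 RPM and 25.8 RPM in wild type on the respective foods and 0 reads in rde-12, at least 92.7-fold and 37.0-fold lower (adjusted p = 0.0107). In the other direction, the cluster led by GAGGTAGAACTATAAACATAAT had 0 reads in wild type and 29.6 RPM and 4.64 RPM in rde-12, at least 43.1-fold and 6.31-fold higher (adjusted p = 0.0372). The cluster led by GTTAGTATGAAAGTACCTCAAA had 0 reads in wild type and 15.6 RPM and 7.196 RPM in rde-12, at least 22.8-fold and 9.77-fold higher (adjusted p = 0.0367). The files pair no sequence with a gene, so these clusters carry no gene name. The count depends on the fit: DESeq2 called 546 clusters, and scaling by library size alone or a model without food called 0. Fits that left out a library also had no food term and held a lone library of a genotype. Their median log2 fold change over clusters ran from -0.62 without rde-12 on cpsf-2 RNAi food to 0.42 without wild type on L4440 food. It was 0.014 in the main fit.

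For food, edgeR's quasi-likelihood test called 0 of 18327 clusters, with 227 higher and 249 lower on cpsf-2 RNAi food at an unadjusted p under 0.05, and DESeq2 called 16. The cluster with the smallest p was led by GATTTTTTAGTTGTCTTGAAGA, a sequence at positions 987 to 1008 of the cpsf-2 contig. The cluster had 271 RPM in wild type and 75.4 RPM in rde-12 on cpsf-2 RNAi food, and 0.687 RPM and 0.279 RPM on L4440 food (edgeR, adjusted p = 0.176). It was singled out after its values were seen. Of the 15 clusters that lie on the contig by most of their sequences, the filter on low counts left 2 for the test. They had 337 and 3379 reads in wild type on cpsf-2 RNAi food. Antisense contig reads of 21 to 23 nt starting with G numbered 116267 there. The 2 are thus a small part of the contig's 22G-RNAs, and the test does not represent the fed gene. Unlike the cluster with the smallest p, these 2 behaved otherwise in rde-12. The additive fit takes a food effect that differs between genotypes as spread, so a missing call does not speak against such an effect. The cluster led by GCAATATCATCATCATCACTGT went from 0 reads to 82.7 RPM in wild type but from 13.4 RPM to 3.48 RPM in rde-12, and that led by GTGAAAGGATTGTAACGGGCT from 0.687 RPM to 829 RPM and from 43.8 RPM to 4.87 RPM. edgeR's quasi-likelihood test called neither of them (adjusted p = 1 for both). By size alone, 439 of 10144 clusters were higher and 613 lower by 2-fold or more on cpsf-2 RNAi food in both genotypes, while 1413 were lower in wild type and higher in rde-12 and 358 the reverse. The food ratios of both genotypes had a Spearman correlation of -0.0839 across clusters.

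miRNAs, which are not made by RNA-dependent RNA polymerases, served as a comparison class. edgeR's quasi-likelihood test of genotype called 0 of 81 miRNAs (lowest adjusted p = 0.0618), with 6 higher and 3 lower in rde-12 at an unadjusted p under 0.05, and DESeq2 called 6 higher and 3 lower. Scaling by library size in place of TMM moved the median log2 fold change of the 81 miRNAs from 0.043 to 0.60. Among 63 miRNAs with at least 100 RPM in a library, 13 were higher and 6 lower by 2-fold or more in rde-12 on both foods, and 10 moved by that size in opposite directions. The highest of the first kind were mir-37, mir-35 and mir-36, followed by mir-48 and mir-44. mir-37 (WBGene00003265, chromosome II from 11537833 to 11537930) had 4.81 RPM in wild type and 68.7 RPM in rde-12 on L4440 food, and 9.08 RPM and 920 RPM on cpsf-2 RNAi food. mir-48 (WBGene00003039, chromosome V from 14364412 to 14364509) had 276 RPM and 7835 RPM on L4440 food and 1286 RPM and 7541 RPM on cpsf-2 RNAi food. mir-44 had 236 RPM and 5712 RPM on L4440 food and 779 RPM and 4054 RPM on cpsf-2 RNAi food. Lowest were mir-50, mir-230, mir-57, mir-236 and mir-43. mir-50 (WBGene00003278, chromosome I from 1738635 to 1738733) had 5972 RPM in wild type and 574 RPM in rde-12 on L4440 food, and 6985 RPM and 662 RPM on cpsf-2 RNAi food. mir-230 had 286 RPM and 72.6 RPM on L4440 food and 623 RPM and 145 RPM on cpsf-2 RNAi food.

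By family, the mir-35 group, which is known from embryos and the adult germline, stood out most. Its 8 members summed to 70.1 RPM in wild type and 421 RPM in rde-12 on L4440 food, and to 255 RPM and 2765 RPM on cpsf-2 RNAi food. Of the 8, 6 were higher in rde-12 on both foods, mir-42 was lower on both (0.575-fold and 0.496-fold), and mir-38 was higher on L4440 food and lower on cpsf-2 RNAi food (0.722-fold). Its members' median log2 fold change of 2.98 lay at the 99.99th percentile of 10000 random lists matched on abundance, a description of these libraries and not a test. With edgeR, 0 of its members passed the threshold over all miRNAs tested, and 1 passed when adjusted over the list alone. The measured let-7 family members, which time larval development, were let-7, mir-48, mir-241 and mir-795. They summed to 3547 RPM and 13230 RPM on L4440 food and to 2779 RPM and 13024 RPM on cpsf-2 RNAi food, with a median of 0.93 at percentile 92.03. All 6 members of the mir-51 family were higher in rde-12 on both foods, with a median of 0.84 at percentile 96.2. Its most abundant member, mir-52 (WBGene00003280, chromosome IV from 14034008 to 14034107), had 5347 RPM and 19194 RPM on L4440 food and 9020 RPM and 15625 RPM on cpsf-2 RNAi food. The mir-64 family had a median of -1.51 at percentile 3.97, though of its 5 members only 1 was lower on both foods and 1 was higher on both. Its member mir-229 (WBGene00003322, chromosome III from 2172452 to 2172566) had 947 RPM and 9003 RPM on L4440 food but 37354 RPM and 2413 RPM on cpsf-2 RNAi food.

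The other lists were mixed. The 4 measured members of the mir-58 family had a median of -0.26 under TMM, which turned to 0.29 under library size scaling, at percentile 31.3. lin-4 had 761 RPM and 421 RPM on L4440 food and 587 RPM and 3805 RPM on cpsf-2 RNAi food. The 2 measured members of its family had a median of 0.44 at percentile 57.97. The 13 measured members of the list of other abundant somatic miRNAs had a median of 0.11 at percentile 67.4. Among them mir-1, a muscle miRNA, had 1330 RPM and 911 RPM on L4440 food and 548 RPM and 6816 RPM on cpsf-2 RNAi food. In these 6 lists besides the mir-35 family, 0 members passed the threshold of edgeR's test over all miRNAs or adjusted over the list alone. To which lists the 9 miRNAs called by DESeq2 belong was not analysed here. The labels give no developmental stage for any library.

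**Figure D3:**
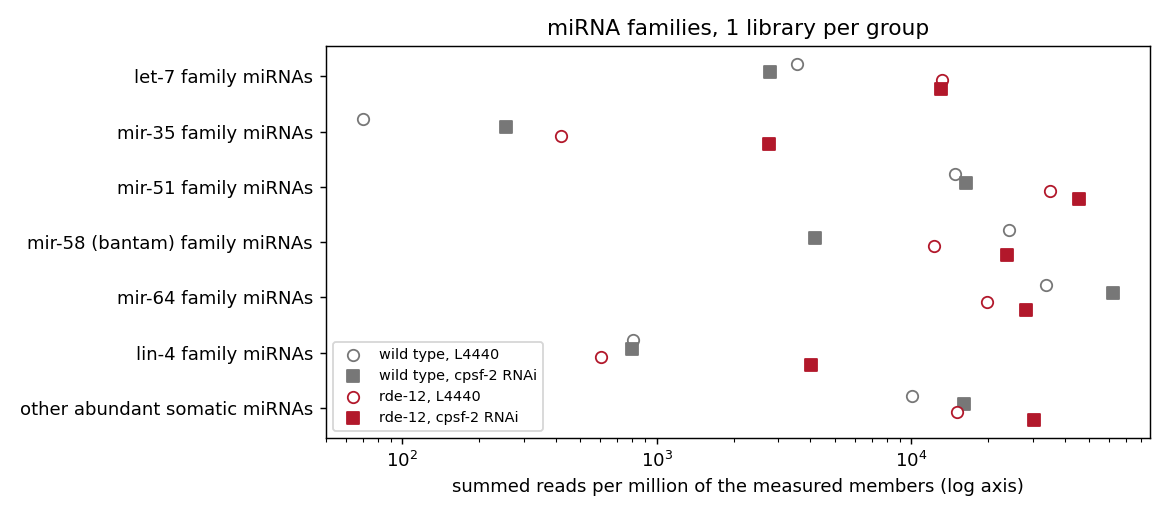
Summed RPM (log axis) of the measured members of each miRNA family in each of the 4 libraries. Grey marks wild type and red rde-12, open circles L4440 food and filled squares cpsf-2 RNAi food; the mir-35 family runs from 70.1 RPM to 2765 RPM.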

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

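The tests of explanations below were chosen after the results had been seen. The differences listed here are between single libraries, and none was tested against replicate spread. Each was listed because the genotype contrast went one way on one food and the other way on the other food, or the food contrast did so between genotypes, beyond counting error.

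The contrast of antisense cpsf-2 reads, rde-12 over wild type, was 10.7 log2 units lower on cpsf-2 RNAi food than on L4440 food (-10.7), since the mutant had 20.4 times the wild-type level on L4440 food and 0.0121 times on cpsf-2 RNAi food. For the loss on cpsf-2 RNAi food, less food RNA taken up was predicted to lower both strands alike. Antisense reads per sense read were 52.3 times higher in wild type (48.7 to 56.3), which argues against a loss shared alike by both strands. It cannot decide on uptake, because it was not tested whether antisense reads scale with the RNA taken up or whether sense reads measure it. Size selection would leave reads of 22 to 23 nt alone, yet these differed by 85.3-fold, and breakdown in the mutant sample would raise its share of 17 to 19 nt reads, yet this was 0.143 times that of wild type. A ligation preference of the barcode would strike other 22G sequences as often, yet 40.7% of those with at least 50 reads in wild type on cpsf-2 RNAi food were 10-fold or more lower in the mutant, against 194 of 199 contig sequences. The values argue against size selection, breakdown and ligation preference as the whole cause. They do so more weakly for ligation preference, because that share is high after picking in the wild-type library. Lower uptake stays open, and a need for RDE-12 in making antisense secondary siRNAs remains a hypothesis from 1 library per group.

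The antisense reads of rde-12 on L4440 food were weighed next. If reads had crossed over from the wild-type cpsf-2 RNAi library after ligation at an even rate, their positions would follow it, yet the correlation was 0.274, while the central 95% of random draws of 1071 reads from that profile began at 0.955. RNA crossing before ligation would give an agreement like that of other clusters between the same libraries. The 22G sequences of the contig had a correlation of 0.198 (bootstrap interval 0.102 to 0.449), which spans the 5th percentile of 106 other clusters (0.262, median 0.770), so this crossing stays open. The library had 63 antisense reads per sense read (39.2 to 109). On cpsf-2 RNAi food the value was 106 in wild type (102 to 110) and 2.03 in rde-12 (1.91 to 2.15). This likeness to the wild-type cpsf-2 RNAi library goes with crossing from that sample. It does not decide, because the interval of wild type on L4440 food, with 4 sense reads, overlaps too (5.95 to 60.5). No biological explanation was tested, and an endogenous set of antisense cpsf-2 RNAs that varies between libraries stays open as well.

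Sense cpsf-2 reads showed a difference of -3.03 log2 units, from 5.18 times the wild-type level on L4440 food, where wild type had 4 reads, to 0.633 times on cpsf-2 RNAi food. The share of 22G reads differed by 0.60 log2 units between foods and that of miRNA reads by 0.42. The share of 26G reads differed by -1.35, with 1.28-fold more on cpsf-2 RNAi food in wild type and 0.502-fold in rde-12. Reads of 17 to 19 nt differed by -4.38 and 5S rRNA reads by -2.71. Summed mir-58 family reads differed by 3.49, with ratios of 0.506 on L4440 food and 5.68 on cpsf-2 RNAi food. Summed lin-4 family reads differed by 2.74, with 0.751 and 5.02.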

How the results depend on the processing

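Scaling to reads of 20 to 26 nt, the classes scaled to miRNA reads, 21U sequences without TMM, reads of 22 to 23 nt, the L4440 level taken off, clusters by 16 or 18 nt, single sequences, exact miRNA sequences and unchecked miRNA length were chosen after seeing the data; the cause of a change was not tested. Reads that match 1 place only, and all antisense reads for the gene lists, were not run, since no read was placed on a genome; all reads in the file became the main scaling. Food in the model already pairs the genotypes within each food. The lower antisense cpsf-2 level in rde-12 on cpsf-2 RNAi food kept its direction in every alternative run for it, and so did the higher 21U share. The lower sense level of the contig did so too, but the L4440 level was not taken off for that strand. The count by human CPSF2, at background in wild type, has no bearing on the sense level. Depth limits clusters near 10 RPM, about 40 reads.

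The antisense fold was 109 scaled to miRNA reads, 206 scaled to 21U reads, 140 for 21 to 23 nt starting with G, 101 scaled to reads of 20 to 26 nt and 137 with the L4440 level taken off. The sense fold was 2.09, 3.93, 1.81 and 1.93 in the first 4 of these and 1.29 for 22 to 23 nt. Class ratios of rde-12 over wild type follow as L4440 food, then cpsf-2 RNAi food. Over distinct sequences they were 1.27 and 1.27 for 21U, 0.876 and 1.27 for 22G, 1.93 and 0.933 for 26G, and 1.29 and 0.821 for miRNAs. Scaled to reads of 20 to 26 nt they were 2.73 and 2.04 for 21U, 0.860 and 0.875 for 22G, 3.35 and 0.881 for 26G, and 1.21 and 1.08 for miRNAs. Scaled to miRNA reads they were 2.27 and 1.88 for 21U, 0.714 and 0.808 for 22G, and, on cpsf-2 RNAi food, 0.813 for 26G. Reads of 22 nt starting with G gave 0.723 and 1.104. The signs that turned were those of the small contrasts: 22G and 26G on cpsf-2 RNAi food and miRNAs on both foods.

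Clusters called by genotype numbered 546 with DESeq2 (72 higher, 474 lower), 293 over all reads of a cluster, 179 with 16 nt and 14 with 18 nt, 43 with 22 nt only, 36 with 10 RPM, 7 scaled to miRNA reads, and 0 with library size only, no filter, genotype only or single sequences. Leaving out a library gave 0 to 1446, the highest without wild type on L4440 food. For 21U sequences every scaling gave 0. By food, DESeq2 called 16 and 16-nt clusters gave 1; leaving out a library gave 0 to 0. For miRNAs DESeq2 called 9, unchecked length gave 1, and leaving out a library gave 0 to 1, the 1 without rde-12 on L4440 food. In those fits a lone library is assumed to vary like the others. With library size only, list medians were 1.48 (let-7), 3.53 (mir-35), 1.40 (mir-51), 0.29 (mir-58), -0.95 (mir-64), 0.99 (lin-4) and 0.67 (other somatic). Clusters lower on both foods numbered 654 with a pseudocount of 5 RPM, 2475 from 2 RPM and 361 from 50 RPM, and higher ones 519, 3394 and 174. More were lower than higher, except from 2 RPM.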

Other observations

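All tests in this part were chosen after their results had been seen. Antisense reads of 21 to 23 nt starting with G that match other known proteins by translation gave a view of further 22G targets. Those of the Tc1 transposase, of a DNA transposon kept silent in the germline, stood at 1272 RPM in wild type and 1230 RPM in rde-12 on L4440 food, a ratio within counting error (0.967, 0.929 to 1.01), and at 2181 RPM and 1667 RPM on cpsf-2 RNAi food (0.764, 0.741 to 0.788). For histone H2A the ratios of rde-12 over wild type were 0.671 (0.626 to 0.719) on L4440 food and 0.740 (0.677 to 0.809) on cpsf-2 RNAi food. The whole 22G class had 0.707 and 1.07 by the same scaling. On L4440 food the ratios of histones H2A and H4 thus lay near that of the class. Other proteins went the other way or differed by food, at 1.68 (1.23 to 2.32) and 1.77 (1.39 to 2.26) for histone H3, 0.659 (0.542 to 0.799) and 1.67 (1.37 to 2.03) for histone H4, and 1.30 (0.760 to 2.24) and 3.03 (1.81 to 5.28) for beta-tubulin. The same count for human CPSF2 was 54.8-fold lower in rde-12 on cpsf-2 RNAi food (41.2 to 74.5). There rde-12 had 48 reads, against 18 for the reversed protein, and it had 57 on L4440 food, so background can set the size of this fold. Beta-tubulin had 20 reads in wild type on cpsf-2 RNAi food, against 10 for its reversed protein. Its ratio there is thus near background too. For the major sperm proteins, made in spermatogenesis, antisense 26-nt reads starting with G numbered 13 in wild type and 89 in rde-12 on L4440 food (8.35-fold, 4.64 to 16.3) and 27 and 40 on cpsf-2 RNAi food (1.40-fold, 0.839 to 2.37). On cpsf-2 RNAi food that difference was within counting error.

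The higher 21U share in rde-12 on both foods was weighed as the last pattern. A ligation preference for a 5′ U would raise 22 to 23 nt reads starting with U as much, yet the 21U ratio exceeded theirs by 1.86-fold on the food where it did so least. A loss of 22G reads from the total would leave 21U reads per miRNA read alike, yet this was 1.88-fold higher in rde-12 on the food with the smaller difference. Of stage, summed let-7 family reads were 3.73-fold higher in rde-12 on L4440 food, the smaller difference, mostly by mir-48 (28.3-fold, with 2.40-fold for mir-241 and 1.52-fold for let-7), and lin-4 was 0.554-fold there, while on cpsf-2 RNAi food mir-48 (5.86-fold), mir-241 (4.81-fold), let-7 (3.45-fold) and lin-4 (6.48-fold) were all higher. Some germline markers moved with the 21U share on both foods, the mir-35 family by its sums (10.8-fold higher on cpsf-2 RNAi food) and sense reads of the major sperm proteins from 9 to 72 reads on L4440 food (7 and 5 for the reversed protein) and from 15 to 87 on cpsf-2 RNAi food (2 and 4). Others did not. In the mir-35 family mir-42 was lower on both foods (0.575-fold and 0.496-fold) and mir-38 lower on cpsf-2 RNAi food (0.722-fold). Antisense 26-nt reads of the major sperm proteins starting with G were within counting error on cpsf-2 RNAi food (1.40-fold, 0.839 to 2.37). Stage or germline content may differ, which the design confounds with genotype and the labels, giving no stage, leave open.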
